A study of Mus musculus with 4 samples.

How the data were processed

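Gene expression was measured by RNA sequencing in 4 samples, control and R848, from 2 mice. Per the labels' protocols, frozen spleen cells recovered for 24 hours in medium with 20% serum, 60 ng/ml SCF, 20 ng/ml IL6 and 20 ng/ml IL3, and cells in 1 ml of medium were treated for 3 days. Per the labels' protocols, samples with an RNA integrity number above 8.0 were sequenced as paired reads of 150 nucleotides. The protocols name both ribosomal RNA depletion and a stranded poly(A) mRNA kit, so which RNA was captured is not settled. Per the submitters' processing notes, kallisto and the mm10 build were used. Versions, the transcript annotation and the step from transcripts to genes were not given in the sources used here.

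The authors deposited log2 values, per the file headers and name log2 FPKM. The lowest value was 0, and undoing log2(value + 1) gave sums from 950530 to 962001 per sample, as TPM would. The values are called FPKM here because the authors named them so. They hold no counts, so a count model was not used, depth is unknown and no counting intervals are given.

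The table had 28192 rows, of which 6398 were at 0 in all 4 samples. Dropping 27 rows whose names a spreadsheet had turned into dates and 91 repeats of 90 symbols (the row with the highest mean was kept) left 28074 symbols. Genes with a mean of at least 1 FPKM over the 4 samples were tested with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with a trended variance prior, two-sided, and Benjamini-Hochberg adjustment over 12612 genes at a threshold of 0.05. The prior had 5.27 degrees of freedom beside 2 residual ones. Coordinates came from GENCODE M21 on GRCm38. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

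The 33 gene lists (887 distinct genes, some in several lists) were written before the data were examined. Of these genes, 12 were matched by an older symbol and 18 were not matched. Lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, adjusted over the lists, beside camera with an estimated correlation and fry. No camera call held with an estimated correlation. That version rests on the 2 residual degrees of freedom, or 1 with the mouse as a block, so a list could hardly pass. For the T cell list the estimated correlation, 0.00513, lay below the preset 0.01, yet the unadjusted camera p went from 1.1e-05 to 0.0457. A call lost with an estimated correlation therefore does not show that correlation between genes accounts for it. With fry the plasma cell and NK cell lists passed (adjusted p = 0.0136 each). Neither did with the mouse as a block (fry adjusted p = 0.0782 and 0.267). The genes named in the text were chosen by a rule fixed before the data were examined. It takes the 10 highest and 10 lowest log2 changes among called genes with the same sign in both mice, without predicted or clone names, and from each list the 2 members that rose and the 2 that fell with the smallest adjusted p. Where no member passed it takes the 2 smallest p, as values only, and it adds Dnmt3a, Flt3, Tlr7, Tlr8 and Myd88. Some genes that the rule takes are not reported here. Other called members named for a list with few calls, and the genes of the closing section, were chosen after their values were seen.

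Control and R848 samples with the same mouse number come from the same animal, per the labels, so the numbers pair the samples. The deviations of the samples of each mouse from their group means correlated at 0.289 across genes. The main fit had no block, and the fit with the mouse as a block (429 higher, 240 lower) is given beside results where it changes a call or moves a count of calls by more than 1.5 times. The alternatives were another pseudocount (0.1), no filter, a stricter filter (5 FPKM), quantile normalization, median log ratio scaling, the block, other variance priors, a minimum 2-fold change, other list tests and leaving out each sample. Leaving 5 abundant rows or the immunoglobulin and T cell receptor rows out was added after seeing the data, as were the block with an estimated correlation and with fry. The rescalings (quantile normalization, median log ratio scaling and the 5 rows left out) were fitted without the block. A gene or list was taken as weaker or stronger under an alternative where it left or entered the threshold, and a count as moved where it differed by more than 1.5 times. The correlation between the mice was taken as moved where it left the 95% Fisher interval over genes.

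The tests were tested on simulated data with the means and spreads of the comparison of R848 with control over 12612 genes, with 200 genes changed. The fit recovered 60.6% of 66 genes changed by 1 on the log2 scale and all 67 genes each at 2 and 3, with 13 false calls among 187. The simulated genes were independent, with moderated spreads and no mouse effect, so these rates need not hold for the data.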

Results

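RNA sequencing measured gene expression in leukaemic spleen cells from 2 mice, named 4050 and 4182, that carry floxed Dnmt3a alleles, the internal tandem duplication of Flt3 and the inducible Mx1-Cre recombinase. Dnmt3a encodes a DNA methyltransferase and Flt3 a receptor tyrosine kinase of blood progenitors, and mutations of both genes recur in acute myeloid leukaemia. The labels describe the Dnmt3a genotype in conflicting ways, as homozygous floxed and as heterozygous, and the genotype was not resolved here. Cells of each mouse were split between vehicle (control, n = 2) and 10 µg/ml R848 (n = 2) for 3 days. R848, or resiquimod, is a small imidazoquinoline known as an agonist of the endosomal RNA sensors TLR7 and TLR8. Which of these receptors it engaged in these mouse cells was not tested. The stated purpose was to find the genes and pathways that change with R848 in these cells. The table gives 1 value per gene and sample on a log2(value + 1) scale, with linear values labelled FPKM that summed to 955395 and 950530 in the controls and to 958275 and 962001 with R848 (mice 4050 and 4182). Read counts per sample were not used here, so the depth behind each value is unknown. Fold changes below are differences of log2(FPKM + 1) and understate the change of genes with low values.

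The genes of the model and of the drug's receptors were examined first. Dnmt3a was at 15.1 ± 0.83 FPKM in control and 13.7 ± 0.956 with R848 (SD, n = 2 each), a log2 difference of -0.13 with limma adjusted p = 0.843. This total gene value does not separate the floxed exons from the rest and so does not check the genotype. Flt3 had a mean below 1 FPKM and was not tested. Its log2 values were 1.36 and 1.55 in control and 0.41 and 0.13 with R848, for mice 4050 and 4182. Tlr7, Tlr8 and Myd88, the adaptor of both receptors, did not pass the test, with log2 differences of 0.33, 0.64 and -0.04 and limma adjusted p of 0.707, 0.522 and 0.966.

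With R848, immunoglobulin and interferon-stimulated genes such as Igkc and Iigp1 were among the largest rises, and Mmp12, Fn1 and Spp1 were among the largest falls. Of 12612 genes tested with limma, 185 were higher and 48 lower at an adjusted p under 0.05, which is 1.85% of the genes, and 218 of them changed at least 2-fold. All 233 changed in the same direction in both mice. With 2 samples per group a gene with opposite changes could hardly pass, so this is not separate evidence of agreement. With the mouse as a block the same test called 429 higher and 240 lower genes, among them all 233. The count depended on how the samples were scaled. It was 76 higher and 12 lower after quantile normalization, and 93 higher and 15 lower after scaling by the median log ratio. With no filter on low values it was 0 and 0, with 1880 genes at an unadjusted p under 0.05 by limma. Of the 233 genes, 76 higher and 12 lower passed under all 3 rescalings tried, and 93 higher and 31 lower passed under none. The rescalings were fitted without the block, with which all 233 passed before rescaling. Under the rescalings, genes at an unadjusted p under 0.05 by limma went from 1454 to between 1524 and 1554. The fewer calls thus did not come with fewer genes at a low unadjusted p. Leaving out the R848 sample of mouse 4182 left 46 higher and 10 lower, and leaving out the R848 sample of mouse 4050 left 78 and 10. With 2 samples per group, the p-values rest on a spread shared across genes.

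**Figure D1:**
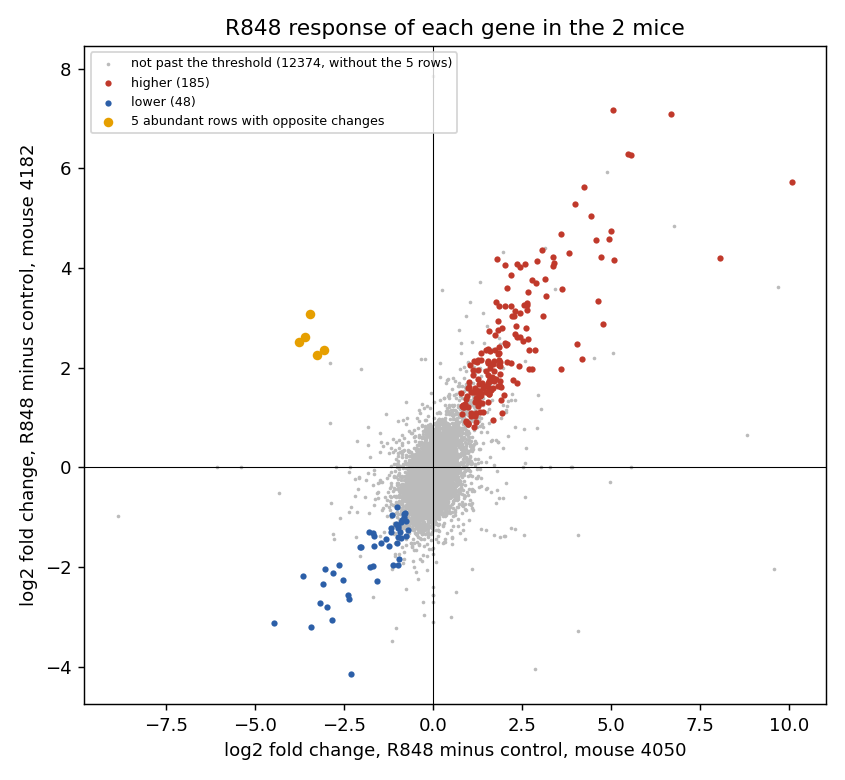
Log2 fold change of each of the 12612 tested genes in mouse 4050 (horizontal axis) and mouse 4182 (vertical axis), with 185 higher genes in red, 48 lower genes in blue, 5 abundant rows with opposite changes in orange and other genes in grey. The called genes lie in the quadrants where both mice moved the same way, which follows from how the test selects them.

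Among the 10 largest rises, 5 belonged to the immunoglobulin system and 5 were interferon or macrophage defence genes, which passed under all 3 rescalings. Igkc, the kappa light chain constant region (GRCm38 chromosome 6, 70726435 to 70726966), rose from 3.82 ± 1.53 to 554 ± 66.8 FPKM (SD, n = 2 each), a log2 difference of 6.88 (SE 0.24, limma adjusted p = 1.2e-04). Iglc2 and Igj (now Jchain, which joins secreted antibody) rose by 4.88 and 4.76. The joining segments Igkj5 and Igkj3 were listed at 0 in both controls, and with R848 Igkj5 was at 1083 FPKM in mouse 4050 and 51.6 in mouse 4182. Both segments lost their call under every rescaling. They span 70723886 to 70723927 (Igkj5) and 70723223 to 70723260 (Igkj3) on chromosome 6. Both are shorter than a read, so their length-scaled values are uncertain. Iigp1, Tgtp1 and Tgtp2, GTPases of cell-autonomous defence, rose by 6.11, 5.92 and 4.73, with Tgtp2 going from 7.26 ± 1.47 to 230 ± 107 FPKM. Tgtp1 and Tgtp2 are near-identical copies whose reads cannot be told apart with certainty. Marco, a macrophage scavenger receptor (chromosome 1, 120474538 to 120505024), rose from 0.724 ± 0.847 to 94.6 ± 11.4 FPKM, a log2 difference of 5.88 (limma adjusted p = 4.8e-04). Irg1 (now Acod1), which makes itaconate, rose by 4.93.

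The 10 largest falls were of genes with different known roles. Spp1, which encodes osteopontin (chromosome 5, 104435118 to 104441050), fell from 599 ± 193 to 79.0 ± 18.9 FPKM, a log2 difference of -2.89 (SE 0.26, limma adjusted p = 0.00368). Atp6v0d2, a proton pump subunit, and Emp1, a membrane protein, had log2 differences of -2.96 and -2.50. Spp1, Atp6v0d2, Emp1 and Pagr1b (-2.72) kept their calls under all 3 rescalings. Klk1b11 (-3.23) kept it under 2 of the 3. Mmp12, a macrophage elastase, Fn1, fibronectin, and Mrc1, the mannose receptor, had log2 differences of -3.80, -3.32 and -2.96. These genes, Ear11 (-2.91) and Slc7a2 (-2.54) lost their calls under each rescaling. The rescalings were fitted without the mouse as a block. With the block and no rescaling, limma adjusted p was 1.2e-06 for Mmp12 and for Fn1 and 8.0e-07 for Mrc1. It was 8.0e-05 for Ear11 and 7.9e-05 for Slc7a2.

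**Figure D2:**
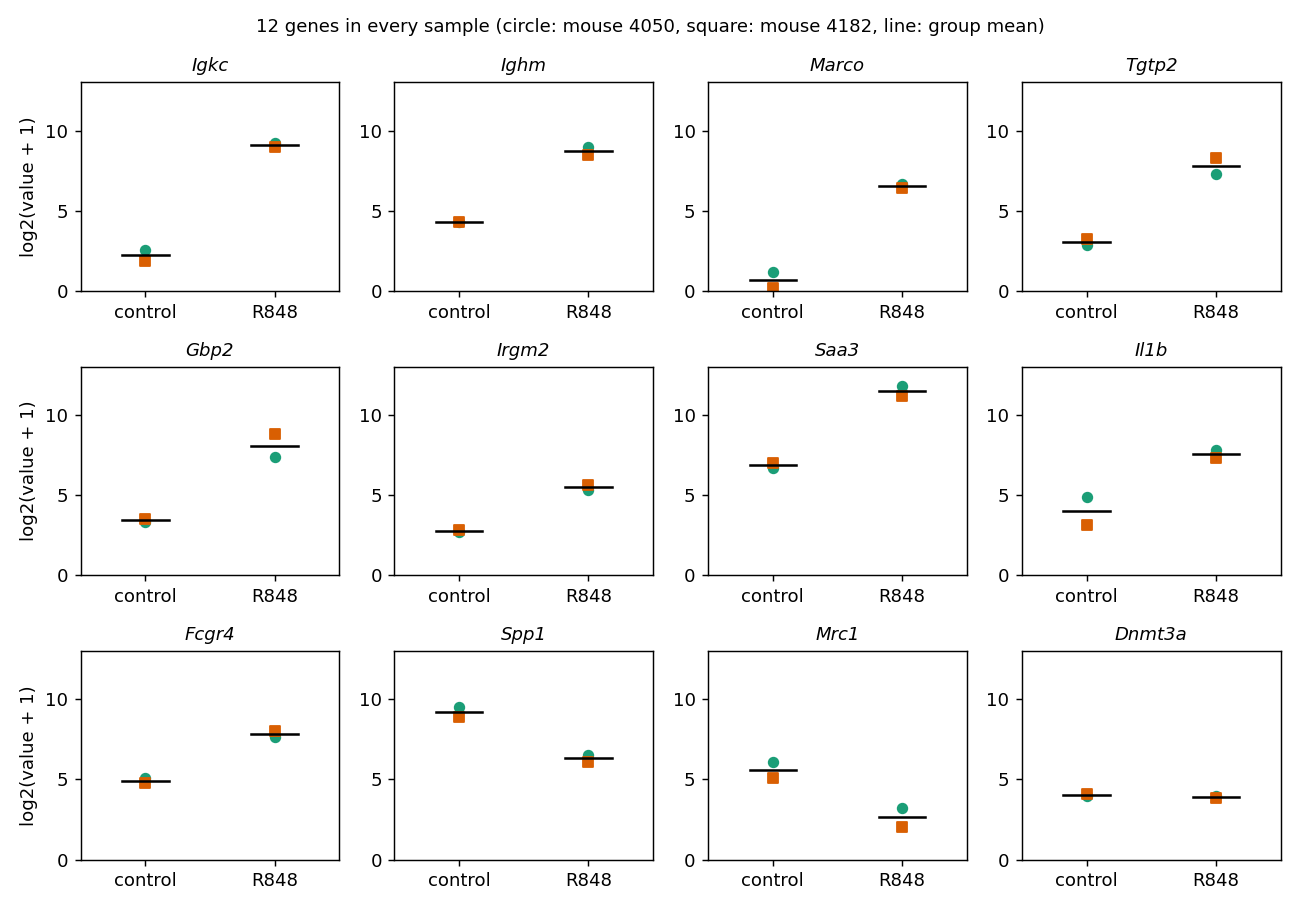
Log2(value + 1) of 12 genes in each of the 4 samples, with control and R848 on the horizontal axis, a circle for mouse 4050, a square for mouse 4182 and a line at the group mean. Igkc, Ighm, Marco, Saa3 and Fcgr4 were higher with R848 in both mice, Spp1 and Mrc1 were lower, and Dnmt3a differed by -0.13 between the group means.

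Interferon-stimulated genes rose as a group. Of 53 tested members, 30 rose and 0 fell by limma over all genes (50 when adjusted over the list alone, 47 with the mouse as a block), and 51 were higher in both mice. Their median log2 change was 1.49, with 1.19 in mouse 4050 and 1.73 in mouse 4182. The camera adjusted p was 6.3e-63 with the preset correlation, and the call was lost with adjusted p = 0.274 with an estimated correlation. With 2 residual degrees of freedom that loss decides little. Gbp2, a guanylate-binding protein, rose from 9.73 ± 0.776 to 300 ± 195 FPKM (log2 difference 4.64), and Irgm2 from 5.83 ± 0.542 to 43.8 ± 7.38 (2.70). Of the 30 members that rose, 10 passed under all 3 rescalings.

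MHC class I presentation genes also rose, with 6 of 20 members past the threshold over all genes, 19 when adjusted over the list alone and 19 with the mouse as a block. Their median was 1.16 (camera adjusted p = 1.8e-23, and adjusted p = 0.339 with an estimated correlation). Psme2, a proteasome activator, and Nlrc5, an activator of class I genes, rose by 1.29 and 1.73, and none of the 6 calls passed under all 3 rescalings. In the MHC class II list 0 of 11 members passed by limma and 0 had an unadjusted p under 0.05. H2-Aa and H2-Ab1 had log2 differences of -0.13 and -0.12 in mouse 4050 and of 0.74 and 0.70 in mouse 4182. Without the R848 sample of mouse 4050 this list passed camera upward, with a median of 0.46 against 0.15 and adjusted p = 7.3e-06.

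Inflammatory genes changed in part. Of 27 cytokines and chemokines, 7 rose and 0 fell (13 and 2 adjusted over the list alone, 13 and 3 with the mouse as a block), with a camera adjusted p = 7.9e-09 and adjusted p = 0.274 with an estimated correlation. Of the 7 members that rose, Cxcl16 alone passed under all 3 rescalings, Cxcl2 passed under 2 and the other 5 under none. Il1b, among those 5, rose by 3.53, to 187 ± 44.0 FPKM, and Cxcl16 rose by 1.96. With the block and no rescaling, limma adjusted p was 1.2e-06 for Il1b. Of 38 NF-kB targets and TLR feedback regulators, 9 rose and 1 fell (14 and 1 adjusted over the list alone), with a camera adjusted p = 1.1e-15 and adjusted p = 0.274 with an estimated correlation. Saa3, an acute phase protein, rose from 115 ± 15.0 to 2926 ± 928 FPKM (4.63), and Slc7a2, an arginine transporter, was the member that fell. Under all 3 rescalings 6 of the 9 rises and 0 of the 1 fall passed. Of 24 TLR7 and TLR8 signalling components, Lgmn and Irf7 rose (3 adjusted over the list alone), both calls ending under the rescalings. That list had a median of -0.02 and a mean of 0.17, so the median differs in sign from the camera direction, which was up with adjusted p = 0.0247 and adjusted p = 0.475 with an estimated correlation. The call also ended without the control or the R848 sample of mouse 4050 (adjusted p = 0.0524 and 0.0645).

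Monocyte and macrophage maturation genes went both ways. Of 36 members, 8 rose and 3 fell (13 and 9 adjusted over the list alone, 14 and 8 with the mouse as a block), and 6 of the rises and 1 of the falls passed under all 3 rescalings. Fcgr4, an activating antibody receptor, rose from 29.6 ± 5.05 to 227 ± 41.8 FPKM (2.90), as did Marco. Klf4 and Trem2, a transcription factor and a lipid receptor of macrophages, fell, with log2 differences of -1.88 and -1.55, and Trem2 kept its call under 1 of the 3 rescalings. The camera adjusted p was 3.6e-05, upward, and adjusted p = 0.475 with an estimated correlation. Neither neutrophil list had a called member by limma. Among 14 granule proteins of early neutrophil precursors, 3 were higher and 1 lower at an unadjusted p under 0.05, with Fcnb at -0.54 and Ms4a3 at 0.48. Among 25 mature neutrophil genes, 6 and 3 were, with Cxcr4 at -0.61 and Lcn2 at 0.74, and with the mouse as a block 6 rose, 1 fell and the camera adjusted p was 0.0208, upward, against adjusted p = 0.832 with an estimated correlation. The medians of this list were 0.26 in mouse 4050 and -0.34 in mouse 4182. It also passed camera without the R848 sample of mouse 4182 (adjusted p = 2.3e-05) and without the control sample of mouse 4050 (0.0133). With the block, Cxcr4 and Lcn2 passed limma with adjusted p of 0.0436 and 0.0146. In the dendritic cell list 0 of 16 passed, 4 were lower at an unadjusted p under 0.05 and 4 fell with the mouse as a block. Its smallest p-values belonged to Socs2 (-0.65) and Itgax (-2.08), which passed limma with the block at adjusted p of 0.0389 and 0.00132. The list passed camera downward without the control sample of mouse 4182 (adjusted p = 0.0146).

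Progenitor and leukaemia genes showed few calls. In the stem and progenitor list 0 of 26 members passed by limma, 3 were higher and 6 lower at an unadjusted p under 0.05, 2 rose and 3 fell adjusted over the list alone, and 2 rose and 4 fell with the mouse as a block. Procr and Ly6a had log2 differences of 1.31 and 3.14 with adjusted p of 0.0783 and 0.0876 by limma, and of 0.00995 and 1.9e-04 with the block. Of 25 FLT3-ITD and STAT5 targets, Ccl5 and Socs1 rose by 1.82 and 1.13 (3 rose and 4 fell adjusted over the list alone, 3 rose and 3 fell with the mouse as a block), and both calls ended under the rescalings.

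Proliferation lists had 0 called members. MYC targets (39), S phase genes (36) and G2 and M phase genes (36) had 0 members at an unadjusted p under 0.05 by limma. Camera placed the S phase list upward with a median of 0.17 (adjusted p = 7.6e-04, and adjusted p = 0.753 with an estimated correlation) and MYC targets upward with a median of 0.10 (adjusted p = 0.0245, and adjusted p = 0.863 with an estimated correlation). The S phase call ended without the control sample of mouse 4182, where its median was -0.01. Without that sample the MYC list turned downward, with a median of -0.11 and adjusted p = 0.368, and its call also ended without the R848 sample of mouse 4050 (adjusted p = 0.215). Ccne2 and Ccne1 were at 0.51 and 0.49, Myc at -0.38 and Phb at 0.34, and Anln and Cenpf at -0.27 and -0.36. Of 26 cell cycle inhibitors and p53 targets 0 passed, 2 were higher and 1 lower at an unadjusted p under 0.05, 1 rose with the mouse as a block, and Fas was at 0.78 (limma adjusted p = 0.0345 with the block) and Cdkn2b at -0.85. Of 26 apoptosis regulators 0 passed over all genes, while 5 rose and 1 fell adjusted over the list alone and with the mouse as a block. Casp1 was at 0.98 (limma adjusted p = 0.002 with the block), and camera was upward with adjusted p = 0.00232 and adjusted p = 0.274 with an estimated correlation.

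Metabolic lists moved by small amounts. For the 73 cytosolic ribosomal proteins the median was -0.23, 72 were lower in both mice, 0 passed by limma and 1 had an unadjusted p under 0.05. Camera was downward with adjusted p = 1.7e-06 and adjusted p = 0.753 with an estimated correlation, and the median stayed below 0 under the rescalings, from -0.18 to -0.08. The camera call ended without the R848 sample of mouse 4050 (adjusted p = 0.131). Rpl12 was at -0.35. Cholesterol synthesis genes (22) had a median of 0.30 with 0 called, 4 higher at an unadjusted p under 0.05 and 2 that rose with the mouse as a block. Sc5d and Idi1 were at 0.62 and 0.60, with limma adjusted p of 0.0333 and 0.0403 with the block, and camera was upward with adjusted p = 1.6e-06 and adjusted p = 0.557 with an estimated correlation. Glycolysis and hypoxia genes (28) had a median of -0.32, with Hif1a up by 1.04 and Ankrd37 down at -1.16, both calls ending under the rescalings (1 rose and 3 fell adjusted over the list alone and with the mouse as a block). Camera was downward there with adjusted p = 1.6e-04 and adjusted p = 0.475 with an estimated correlation. Fth1, the ferritin heavy chain, rose by 1.32 as the called member of 21 NRF2 and oxidative stress genes, a call that ended under the rescalings (2 rose adjusted over the list alone and with the mouse as a block; camera adjusted p = 0.0152, and adjusted p = 0.475 with an estimated correlation). That camera call ended without the R848 sample of mouse 4182 (adjusted p = 0.134). Respiratory chain genes (41), stress response genes (29) and immediate early genes (18) had 0 called by limma. At an unadjusted p under 0.05, 1 respiratory chain gene was higher, 2 stress response genes were higher and 5 lower, and 1 immediate early gene was higher and 2 lower. With the mouse as a block, 2 stress response genes and 1 immediate early gene fell, as they did adjusted over the list alone. Cycs and Cox5a were at 0.42 and 0.35, Vldlr and Trib3 at -1.24 and -0.89, and Egr2 and Atf3 at -2.12 and 0.85. With the block, Vldlr, Trib3 and Egr2 passed limma at adjusted p of 0.00513, 0.0282 and 8.9e-04. The respiratory chain list passed camera upward without either sample of mouse 4050 in turn (control, adjusted p = 0.0342, and R848, 0.0054).

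Markers of other cell types were measured because the samples were not sorted for leukaemic cells, as far as the labels say. Plasma cell markers had the highest median of the 33 lists, 2.46, with 4 of 8 members rising (Igkc, Iglc2, Igj and Mzb1; 7 adjusted over the list alone) and all 8 higher in both mice. All 4 calls passed under all 3 rescalings. B cell markers rose in 4 of 11 members (among them Ighm, Ms4a1 and Cd79a; 7 adjusted over the list alone) with a median of 0.80, and 3 of the 4 calls passed under all 3 rescalings. Ighm, the IgM heavy chain, went from 18.4 ± 0.0182 to 436 ± 109 FPKM (4.47), and Ms4a1, which encodes CD20, from 0.247 ± 0.0936 to 6.25 ± 1.69 (2.52). T cell markers rose in 3 of 13 members, Trbc1, Cd3g and Trac, from levels below 0.5 FPKM to between 2.82 and 3.30 FPKM, and these calls ended under the rescalings. Of 6 NK cell markers 0 passed, 3 had an unadjusted p under 0.05 and 3 passed adjusted over the list alone, and 2 rose with the mouse as a block, with Xcl1 at 1.49 and Il2rb at 1.01 (limma adjusted p of 0.00499 and 0.0457 with the block). Camera was upward for plasma cells (adjusted p = 1.1e-17), B cells (6.2e-09), T cells (3.7e-05) and NK cells (7.6e-04), each with adjusted p = 0.274 with an estimated correlation. Mast cell and basophil markers (16) had 0 called, 3 with an unadjusted p under 0.05, 2 that rose with the mouse as a block, and a median of 0.59 in mouse 4050 and -0.26 in mouse 4182, with Fcer1a at 1.30 and Prss34 at 0.91 (limma adjusted p of 0.0049 and 0.00208 with the block). Camera was upward for them with adjusted p = 0.00888 and adjusted p = 0.753 with an estimated correlation, and the call ended without the R848 sample of mouse 4050 (adjusted p = 0.633). Of the 8 plasmacytoid dendritic cell markers, Ly6d rose, listed at 0 in both controls and at 4.38 ± 2.06 FPKM with R848 (2 rose and 3 fell adjusted over the list alone, 2 rose and 1 fell with the mouse as a block). Pf4 of the 8 megakaryocyte markers rose by 2.02, a call kept under 2 of the 3 rescalings (2 rose and 1 fell adjusted over the list alone and with the mouse as a block). Vcam1 rose by 1.71 as the called member of 6 stromal markers, a list that passed camera upward without the control sample of mouse 4182 (adjusted p = 0.0133) and without the R848 sample of mouse 4050 (0.0356). Erythroid markers (6) had 0 called and 0 with an unadjusted p under 0.05, with Hbb-b1 at -0.44 and Tfrc at 0.38.

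**Figure D3:**
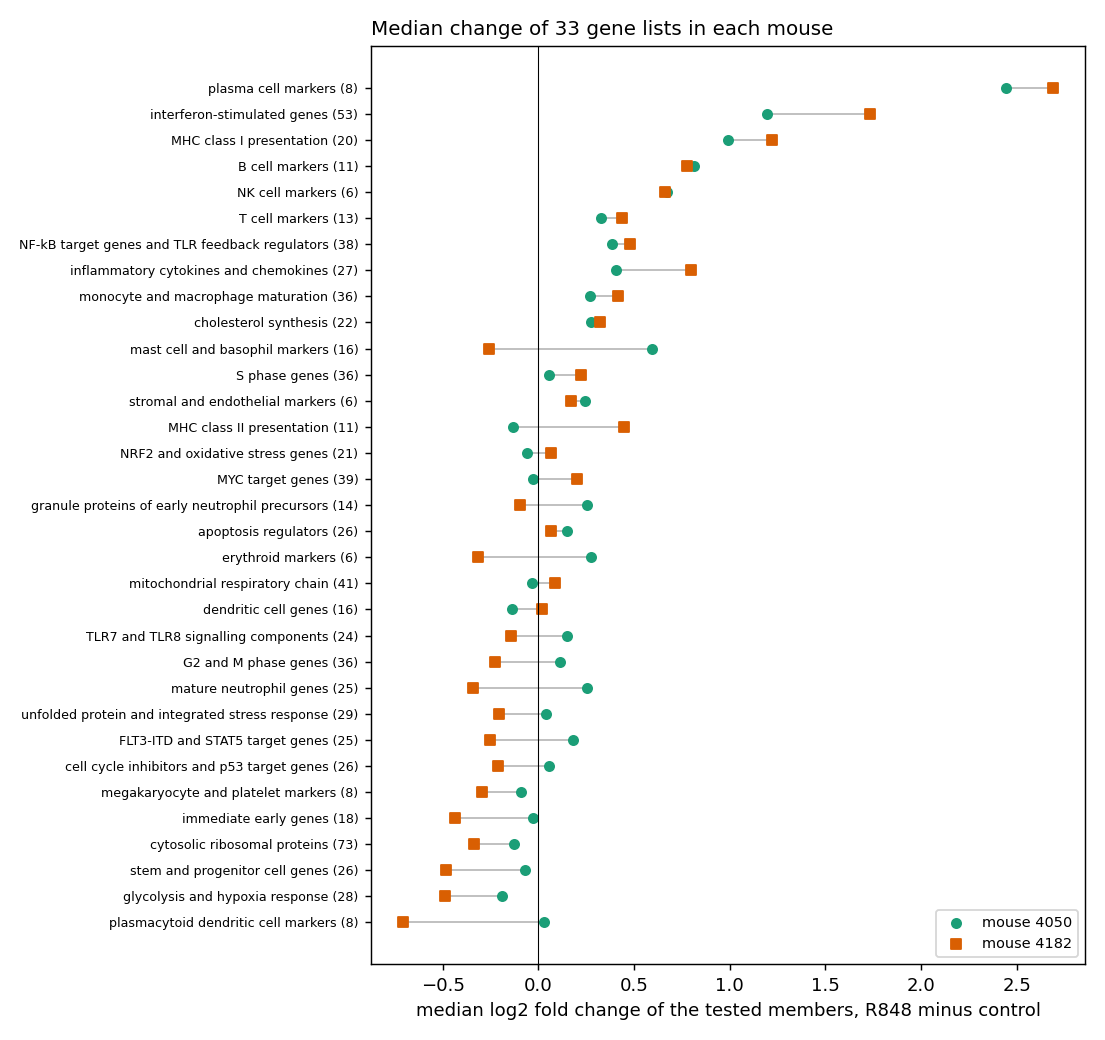
Median log2 fold change of the tested members of each of 33 gene lists in mouse 4050 (circles) and mouse 4182 (squares), with the number of tested members in brackets. Plasma cell markers have the highest medians, 2.45 and 2.69, followed by interferon-stimulated genes at 1.19 and 1.73.

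The response was compared between the mice. Across the 12612 genes, the log2 fold changes of the mice correlated with Pearson r = 0.559 and Spearman rho = 0.385, and 60.9% of genes had the same sign. These are correlations across genes, which are not independent replicates. The median change of all genes was 0.00 in mouse 4050 and -0.16 in mouse 4182, and the 10 largest values took 21.0% of the summed value in the R848 sample of mouse 4182 against 13.1% to 14.8% in the other samples. The first principal component held 54.8% of the variance and separated R848 from control, and the next held 29.1% and separated the mice. With 1 sample per mouse and treatment, a difference between the mice in their response could not be tested.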

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

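The tests in this part were chosen after the results were seen, except the search for sequence shared between rows, which was written before it was run.

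Among genes with a mean of at least 1 FPKM, 9 changed in opposite directions in the mice by at least 2 on the log2 scale in each. The bound was set after seeing the data, each mouse has 1 sample per treatment, and the difference was not tested. The change in mouse 4182 minus that in mouse 4050 was 5.53 for AA474408, 6.54 for Gm12913, 6.30 for Gm15564, 5.44 for Gm15662 and 6.22 for Lars2, which fell in mouse 4050 and rose in mouse 4182. It was 5.01 for the T cell receptor segment Traj21, -11.62 for the immunoglobulin segment Igkj4, and -6.90 and -7.35 for the predicted genes Gm10491 and Gm11084.

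The first 5 rows are abundant. Together they took 2.11% and 2.20% of the summed value in the controls of mice 4050 and 4182, 0.228% in the R848 sample of mouse 4050 and 12.5% in that of mouse 4182. The 3 rows with reference transcripts were AA474408, Gm15564 and Lars2. Of these, 0 aligned to the mitochondrial ribosomal RNAs, and 0 pairs shared at least 100 bases at 90% identity. For these 3 rows this argues against mitochondrial ribosomal RNA and against one shared read sequence. Gm12913 and Gm15662 were not searched. Gm15662 alone took 8.22% of the summed value in the R848 sample of mouse 4182 and 1.48% in the control of mouse 4050. The search therefore leaves the source of most of the share open. Different stretches of one longer RNA, such as the nuclear ribosomal RNA precursor, stay open because that sequence was not used here. With the 5 rows left out and each sample rescaled, the median change in mouse 4182 went from -0.16 to -0.0353, so the share these rows take may set the lower values of other genes there. No biological explanation was tested.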

How the results depend on the processing

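Leaving out the 5 abundant rows or the receptor rows, and the block with an estimated correlation or with fry, were added after seeing the data. Against 185 higher and 48 lower genes, no filter gave 0 and 0 (limma, 1880 genes at an unadjusted p under 0.05), quantile normalization 76 and 12, median log ratio scaling 93 and 15, the 5 rows left out 90 and 17, the replicate block 429 and 240, and a robust prior 99 lower. Under the 3 rescalings the prior degrees of freedom fell from 5.27 to between 3.25 and 3.50 while genes at an unadjusted p under 0.05 went from 1454 to between 1524 and 1554, and without a filter they were 2.30. What lowered them was not tested. Leaving out 1 sample gave 46 to 259 higher and 10 to 136 lower genes. The 46 came without the R848 sample of mouse 4182, and 33 higher and 3 lower genes passed in all 4 such fits, where a lone sample is assumed to vary like the other group.

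Of 44 called genes named by the rule, 0 passed with no filter, 22 with quantile normalization, 24 with median log ratio scaling, 25 without the 5 rows and 18 to 44 with 1 sample left out. Of the 33 lists, 16 were higher and 2 lower by camera with the preset correlation. The version with an estimated correlation had 2 residual degrees of freedom, or 1 with the replicate block, and could hardly call a list. An estimated correlation gave 0 and 0, also with the replicate block, fry gave 2 and 0, or 0 and 0 with the replicate block, no filter gave 4 lower, and leaving out 1 sample gave 15 to 17 higher and 1 to 3 lower. The MYC target list turned downward, with a median of -0.11, without the control sample of mouse 4182. Its medians ran from -0.11 to 0.32 with 1 sample left out. The correlation between the mice, 0.559, was 0.519 with a pseudocount of 0.1, 0.495 with no filter, 0.603 with the stricter filter and 0.546 without the receptor rows. It has no value with 1 sample left out, and the block leaves it as it is. The replicate block raised the mature neutrophil list past the threshold and changed no other list's call by camera. With 1 sample left out, the MHC class II, mature neutrophil, dendritic, respiratory chain and stromal lists entered the threshold in some fits. The causes of the other changes were not tested, and the depth reached in each sample is unknown.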

Other observations

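The tests in this part were chosen after the results were seen, except the search for other RNAs without a poly(A) tail, which was written before it was run. Genes named here were chosen after their values were seen.

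Among immunoglobulin and T cell receptor rows 16 of 44 were called, and 4 of 8 plasma cell markers rose, with all 8 higher in both mice. Of the 16 calls, 6 passed under all 3 rescalings and 10 under none, and the 4 plasma cell calls passed under all 3. Igkj4 went opposite ways in the mice. The calls include Igkj5 and Igkj3, joining segments shorter than a read, whose length-scaled values are uncertain. A shift of all genes by the scaling is argued against by its size. The median change of all genes was 0.00 in mouse 4050 and -0.16 in mouse 4182, against 2.46 for the plasma cell list. Median log ratio scaling could therefore move that list only little. Its median after that scaling, 2.50, with 2.43 in mouse 4050 and 2.81 in mouse 4182, is not separate support. A larger share of B lineage cells cannot be told apart from higher levels per cell. The B cell list had a median of 0.80 with a member SD of 1.43. Over its 7 members at 1 FPKM or more in control the median was 0.54. Several of these (Cd37 at 68.4 FPKM) are high before treatment and would hide a small share. The 4 members outside these 7 lie below 1 FPKM in control. That left 4 members from 1 to 10 FPKM, too few to decide. A response of B lineage cells to R848 stays open and was not tested.

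Replication-dependent histone genes were lower with R848. Over 60 such rows the median log2 change was -0.74 (member SD 0.22), 58 were lower in both mice, and limma called 11 lower and 0 higher, or 41 with the mouse as a block. Of the 11 calls, 2 passed under all 3 rescalings and 9 under none. The median stayed between -0.70 and -0.66 under the 3 rescalings. The S phase list did not fall with the histone rows, with a median of 0.17 (member SD 0.18), or -0.01 without the control sample of mouse 4182. This goes against fewer cells in S phase but does not exclude it. The list holds RNA levels, and the share of cells in S phase was not measured. A move of reads between near-identical copies is argued against because the summed histone value changed by -0.65 in mouse 4050 and -0.76 in mouse 4182. Histone messages lack a poly(A) tail, and a lower yield of such RNA may account for the fall, which cannot be told apart here because 0 of 9 other RNAs without a tail were among the tested genes. An effect of R848 on histone messages stays open too, as untested.

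One hypothesis is that the interferon-stimulated genes answered mainly to interferon gamma. Ifng itself rose from 0.0182 to 10.1 FPKM (limma adjusted p = 0.0225). This call ended under each rescaling, fitted without the mouse as a block (limma adjusted p = 0.113, 0.0972 and 0.0906). With the block and no rescaling, limma adjusted p was 6.3e-05 for Ifng. The median change of 17 genes preferred by interferon gamma exceeded that of 14 genes preferred by type I interferon by 1.32 (2.95 against 1.62, two-sided permutation p = 0.00601). This decides nothing, since the classes were written after the highest genes had been seen, and Ciita, a gamma target, had a log2 difference of 0.26 with limma adjusted p = 0.746.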
